A study of Pelodiscus sinensis with 12 samples.

How the data were processed

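Liver RNA from 12 samples of the Chinese soft-shelled turtle (Pelodiscus sinensis) was measured by RNA sequencing. Groups were taken from the sample labels: females and males on a normal diet, called control here, and females and males on a diet with Bacillus subtilis B10, called B10, with 3 samples in each of the 4 groups. Replicate numbers are those in the labels. Per the labels' protocols, total RNA was extracted with Trizol, checked for integrity, enriched for poly(A) RNA and sequenced in paired-end mode on an Illumina NovaSeq; that protocol text speaks of adipose tissue, while the tissue label of every sample is liver. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used. The genome build is not given in the sources used here, and no coordinates are printed.

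The authors deposited 1 table with 24646 genes that holds, for each sample, FPKM values and whole-number estimated counts per gene, per the file headers. No normalization of the deposited estimated counts is recorded, and their totals ran from 40.9 to 51.2 M (mega) units per sample. Low values were piled up at 4, 8 and 12 (3767 values of 4, against 831 of 3 and 717 of 5), a pattern that fades at higher values (1058 of 16, against 1419 of 15). A read pair was therefore assumed, not known, to be worth 4 units in intervals, floors and the standard errors of counting noise, and the test was also run on the counts divided by 4. An FPKM of at most 0.0001 with a count of 0 was read as 0. Gene symbols, descriptions, Gene Ontology terms and KEGG pathways came from the same table, in which 485 rows share their gene name with another row. The authors' handling of reads that match several genes is not given in the sources used here, so values of near-identical copies such as vitellogenins, hemoglobins and avidin-like genes are uncertain.

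Before the data were examined, the table was assumed to hold FPKM only, and the tests, sample groups, gene lists, rule for named genes and a first set of alternatives were fixed on that assumption, with limma as the test. As estimated counts were found in the table, the main test was changed to edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on counts rounded to whole numbers, and the limma test on log2(FPKM + 1) was kept as an alternative. Genes with an FPKM of at least 1 in at least 3 samples were tested, 11751 in all, which held at least 99.4% of the counts of every sample. Libraries were scaled with TMM factors, 1 model with 4 group means was fitted to all 12 samples, and 5 contrasts were tested: the diet effect averaged over sexes, in females and in males, the difference of the diet effect between sexes (females minus males), and the sex difference averaged over diets (females minus males). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05; "edgeR adjusted p" stands for this value throughout. Expression levels are scaled counts (CPM), as mean ± SD, and log2 changes are given ± SE.

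Gene lists for pathways and cell types were tested with camera at a preset correlation between genes of 0.01 on log2 CPM (prior count 2), adjusted over the 39 lists tested in a contrast, and again with an estimated correlation and with fry. Lists of pancreatic acinar markers (1 of 7 members tested), skeletal muscle markers (1 of 7) and gonad and germ cell markers (2 of 12) fell under the minimum of 3 tested members and were not tested. Annotation terms with 10 to 500 genes were tested by a one-sided Fisher's exact test against the 10957 tested genes that have a term, for each direction with at least 10 called genes. Genes named in the text are, per contrast, up to 10 in each direction with the largest change among those past the threshold whose groups did not overlap; where fewer than 5 were left, those with the lowest p were added up to 5 and are given as missing the threshold. For the difference of the diet effect between sexes, the 5 of each sign with the lowest p were taken. The 4 members with the lowest p and the most abundant member of each described list, and a short set of metabolic, antioxidant and immune genes, complete the rule, and genes named outside it are said to be chosen after their values were seen. A few genes that this rule selects are not reported here. CYP7A1, IL1B, IL8 and IL10 of that set have no row under these symbols, and TNF was below the expression filter.

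On simulated counts with 200 genes changed, the edgeR test recovered 49% of genes changed 2-fold and 83% of those changed 4-fold for the averaged diet effect, 18% and 79% in females, 14% and 75% in males, and 54% and 88% for the sex difference, and 5.3% to 7.6% of its calls were false. The simulated libraries were independent of each other and took their spread from the fit to all 12 samples. These shares therefore do not cover libraries that are close to sums of others, as described below for 12 samples that may not all be separate. Alternatives were other filters, scalings and pseudocounts, DESeq2 1.42.0, a block for the replicate number, fits of single sexes, other thresholds, and fits without each sample in turn. DESeq2, counts divided by 4, library size scaling and the fits without several libraries were added after seeing the data. Intervals and floors cover counting error only.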

Results

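The data set compares the liver transcriptome of Chinese soft-shelled turtles on a normal diet with that of turtles on a diet supplemented with Bacillus subtilis B10, a strain of a spore-forming bacterium, in both sexes. The 12 libraries fall into 4 groups of 3. Total counts were 47.6 ± 3.2 M units in control females, 46.6 ± 2.9 in control males, 43.7 ± 1.2 in B10 females and 41.7 ± 0.7 in B10 males (SD, n = 3). Spearman correlations across genes ran from 0.914 to 0.986 within groups (12 pairs) and from 0.882 to 0.955 between groups (54 pairs). Vitellogenins, the egg yolk precursors that the liver makes under estrogen, took 23.1% ± 3.79 of the counts in control females and 21.0% ± 7.81 in B10 females, against 0.172% ± 0.282 in control males and 0.0163% ± 0.00924 in B10 males (SD, n = 3).

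Some libraries stood apart from their group. The library labelled control male replicate 5 held 0.498% vitellogenin counts (95% Wilson interval 0.494% to 0.502%), against 0.027% or less in the other male libraries. It also held all 17 transcripts, chosen after seeing the data, that were found in all 6 female libraries and had 0 counts in the other 5 male libraries. Summed, they stood at 133.2 CPM in it, between 139.5 and 171.8 CPM in the female libraries and at 0 in the other males. Among them was a Ran-like transcript (LOC102446816), a copy of a small GTPase of nuclear transport, at 41.2 ± 5.13 CPM in females (SD, n = 6) and 39.8 CPM in this library. B10 female replicate 3 held 11.9% vitellogenin counts (11.92% to 11.96%), the lowest share of the female libraries. On the first principal component (31.9% of the variance) it stood at 3.5 and the library labelled control male replicate 5 at -0.2, between the other females (-71.1 to -33.8) and the other males (35.5 to 56.6). The replicate 6 libraries of control females and of B10 males were close to weighted sums of the other libraries of their group. Of their genes, 5.8% and 4.4% lay more than 3 standard errors of counting noise off the sum, against 34.6% to 57.2% in the 6 libraries of the other 2 groups. In them 59.6% and 63.6% of genes lay between the other libraries of the group, against 19.1% to 49% there. Each count below is therefore also given without the replicate 6 libraries and without the library labelled control male replicate 5. A library that is a weighted sum of others adds no separate sample and narrows the spread of its group. If the replicate 6 libraries are such sums, the adjusted p-values printed below from all 12 libraries are too small.

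**Figure D1:**
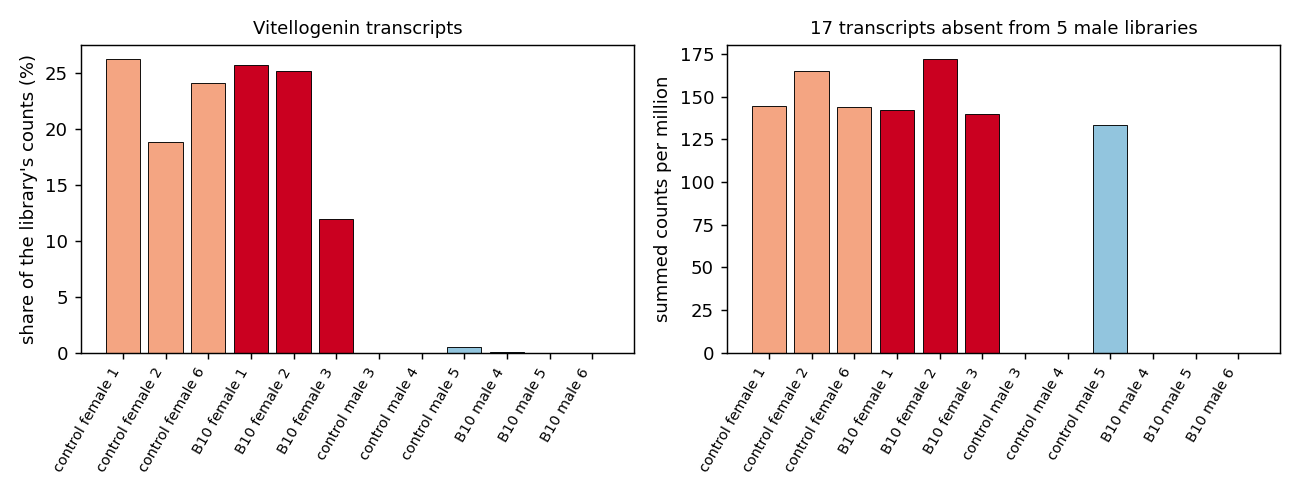
Vitellogenin share of each library's counts in percent (left) and summed CPM of the 17 transcripts with 0 counts in 5 male libraries (right); each bar is 1 library, coloured by group. The library labelled control male replicate 5 has 0.498% vitellogenin and 133.2 CPM of the 17 transcripts.

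**Figure D2:**
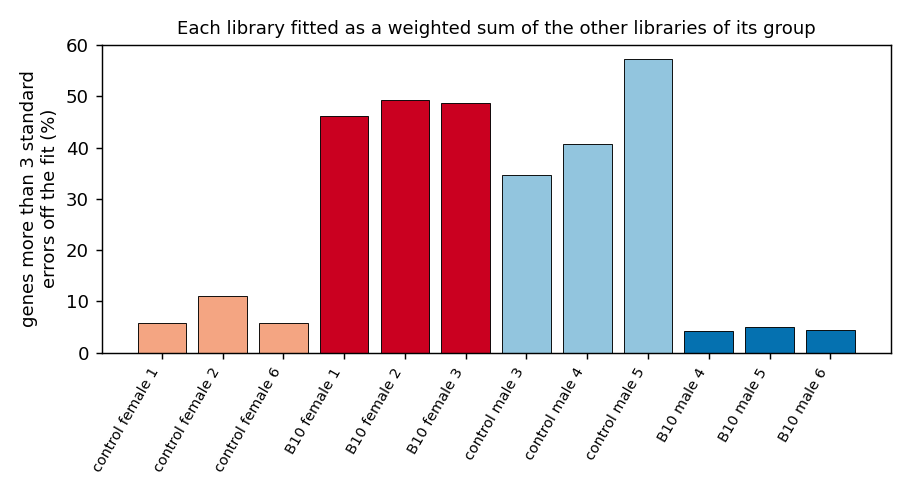
Percentage of tested genes that lie more than 3 standard errors of counting noise off the best weighted sum of the other libraries of the same group; each bar is 1 library, coloured by group. The replicate 6 libraries of control females and B10 males stand at 5.8% and 4.4%, and the other libraries of these 2 groups are low as well since their best sum includes replicate 6.

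The question of the diet averaged over sexes was which liver transcripts differ between B10 and control animals. FOS, a component of the AP-1 transcription factor, rose on the B10 diet by 2.47 ± 0.39 (log2, SE; edgeR adjusted p = 0.04), with 6.79 ± 2.17 CPM in control and 25.2 ± 21.6 in B10 females, and 6.69 ± 3.32 in control and 55.8 ± 7.72 in B10 males (SD, n = 3). Its partner JUNB rose by 1.22 ± 0.17 (edgeR adjusted p = 0.024), from 27.9 ± 3.38 to 51.5 ± 15.2 CPM in females and from 26.1 ± 7.58 to 77.3 ± 5.37 in males. NFKBIA, the inhibitor that NF-kB induces to hold itself in the cytoplasm, rose by 0.96 ± 0.14 (edgeR adjusted p = 0.0276). ATP1B1, the beta subunit of the sodium pump, rose by 1.34 ± 0.16 (edgeR adjusted p = 0.0152), from 16.9 ± 1.38 to 58.0 ± 5.54 CPM in females and from 28.4 ± 1.64 to 53.0 ± 18.5 in males.

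TUBB6, a beta-tubulin, rose by 1.67 ± 0.22 on the B10 diet (edgeR adjusted p = 0.0186). No gene that fell met the rule for named genes. HAO2, a peroxisomal hydroxyacid oxidase, had a log2 change of -0.57 (edgeR adjusted p = 0.0555). BYSL, a ribosome assembly factor, stood at -0.97 (0.0636), AHR, the aryl hydrocarbon receptor, -0.47 (0.0815), AFDN, a junction protein, -0.93 (0.0848) and LRRCC1 -0.67 (0.104), all short of the threshold. Chosen after their values were seen, LOC102463208, annotated as toll-like receptor 5, a sensor of bacterial flagellin, rose by 4.39 ± 0.51 (edgeR adjusted p = 0.0152), and LOC102449082, annotated as the chemokine CXCL11, rose by 2.62 (edgeR adjusted p = 0.0414). The row with the symbol TLR5 had a change of 2.20 ± 0.69 that missed the threshold (edgeR adjusted p = 0.279).

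**Figure D3:**
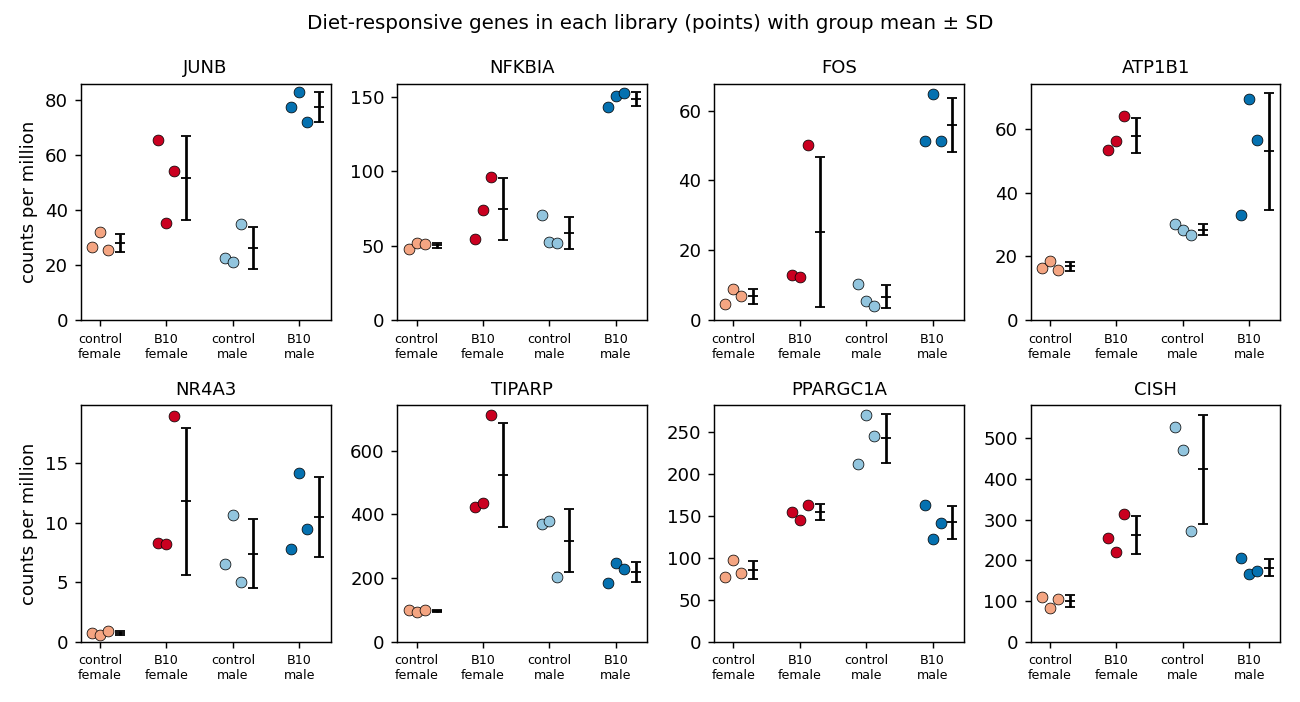
Expression (CPM) of 8 genes in each library (points, 3 per group) with the group mean and SD beside them. JUNB, NFKBIA, FOS and ATP1B1 passed the threshold in the averaged diet effect, NR4A3 and TIPARP in females, and TIPARP, PPARGC1A and CISH in the difference of the diet effect between sexes, with values down to 0.73 ± 0.18 CPM for NR4A3 in control females.

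Of the lists fixed in advance, 4 were called for diet averaged over sexes. Other splits of the samples within each sex gave a median of 6 called lists. Immediate early genes, transcribed within minutes of a stimulus, had 17 of 19 members higher (median log2 change 0.57, camera adjusted p = 1.15e-07). Singly, 3 rose, which were FOS, JUNB and NR4A3 (2.26 ± 0.30, edgeR adjusted p = 0.0186). In this list 7 rose when adjusted over the list alone. Toll-like receptor and NF-kB genes had 13 of 16 members higher (median 0.52, camera adjusted p = 0.00139). Over all genes 1 rose, NFKBIA, and 6 rose and 2 fell when adjusted over the list alone. RELB, an NF-kB subunit, had a change of 0.72 ± 0.20 (edgeR adjusted p = 0.214) and NFKBIZ, another NF-kB regulator, -0.95 ± 0.34 (edgeR adjusted p = 0.342). Granulocyte markers had 8 of 10 members higher (median 0.84, camera adjusted p = 0.00139). None of them rose over all genes and 2 rose when adjusted over the list alone. CSF3R, the receptor of granulocyte colony-stimulating factor, missed the threshold (edgeR adjusted p = 0.152). Cytosolic ribosomal proteins had 59 of 65 members lower by a small amount (median -0.12, camera adjusted p = 0.0017), with none changed singly over all genes or over the list alone. With an estimated correlation between genes, none of these calls held (adjusted p = 0.449 for the first 3 lists and adjusted p = 0.959 for ribosomal proteins). The number of lists was 10 without B10 female replicate 1, 8 without control male replicate 5 and 7 without B10 female replicate 2 or control male replicate 4. The ribosomal call was lost without control female replicate 2 (camera adjusted p = 0.81) and without B10 female replicate 2 (0.111). The other 35 lists, among them cholesterol synthesis, fatty acid synthesis, bile acids and antioxidant genes, missed the threshold (camera adjusted p from 0.162 to 0.996), of which 4 passed it without the library labelled control male replicate 5: antioxidant and glutathione genes (0.0209), complement (0.0111), amino acid breakdown and the urea cycle (0.00276) and acute phase and plasma proteins (0.0428), all higher.

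By edgeR's quasi-likelihood test, 18 genes changed with diet averaged over sexes, 17 higher and 1 lower, and 16 of them by at least 2-fold. Of the 18, 12 had no overlap between diets within either sex, where chance gives 0.5% of genes and 1.4% of tested genes showed it. An unadjusted p under 0.05 was reached by 1254 genes, where chance gives 588, and DESeq2 called 301. The split of higher and lower calls was 15 and 4 on TPM, 37 and 10 after quantile normalization and 204 and 97 by DESeq2. It leaned the other way with sample weights (612 and 1059). Among the genes at an unadjusted p under 0.05 by edgeR, 708 were higher and 546 lower. The only annotation term called was the Toll-like receptor signaling pathway (4 of 77 genes, 0.11 expected, adjusted p = 0.00471 by Fisher's exact test), through FOS, NFKBIA, LOC102449082 and LOC102463208. Without both replicate 6 libraries edgeR called 0 genes (617 at an unadjusted p under 0.05, where chance gives 588), and the same 4 lists remained called. All 18 genes kept their sign and an unadjusted p under 0.05. That is no independent check, as the libraries left were among those that chose the 18 genes. Without the library labelled control male replicate 5 edgeR called 12 genes, 9 of them among the 18. In that fit 8 lists were called, the 4 above and the 4 that missed the threshold otherwise. None of the 6 genes called here under the rule for named genes kept its call in all 12 fits without 1 library. Leaving out 1 library gave 2 genes without control female replicate 1, 3 without control female replicate 6, 2 without B10 male replicate 5, 1 without B10 male replicate 6 and 44 without B10 female replicate 1.

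Within females, NR4A3, an orphan nuclear receptor of the immediate early class, rose on the B10 diet by 4.01 ± 0.46 (log2, SE; edgeR adjusted p = 0.0174), from 0.73 ± 0.18 to 11.8 ± 6.17 CPM (SD, n = 3), and its paralog NR4A1 rose by 2.16 ± 0.37 (edgeR adjusted p = 0.0432). TIPARP, a poly(ADP-ribose) polymerase family member induced through the aryl hydrocarbon receptor, rose by 2.44 ± 0.28 (edgeR adjusted p = 0.0174), from 96.7 ± 4.18 to 523.3 ± 163 CPM. GLUL, glutamine synthetase, rose by 3.17 ± 0.55 (edgeR adjusted p = 0.0432), from 5.08 ± 1.93 to 45.7 ± 7.64 CPM, and ALAS1, the rate-limiting enzyme of heme synthesis, rose by 2.32 ± 0.32 (edgeR adjusted p = 0.0174). SGK1, a kinase under corticosteroid control, rose by 2.11 ± 0.37 (edgeR adjusted p = 0.0432).

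Other rises in B10 females, some of them larger, were those by edgeR of TNFRSF6B, a decoy receptor of the tumor necrosis factor family (3.41 ± 0.51, adjusted p = 0.0263), TNFSF15, a ligand of that family (2.62 ± 0.46, adjusted p = 0.0432), OTOGL (2.46 ± 0.35, adjusted p = 0.0174) and the homeobox gene VENTX (2.23 ± 0.37, adjusted p = 0.0342). Among the genes that fell were ARL3, a small GTPase of cilia (-1.71 ± 0.27, edgeR adjusted p = 0.0332), ALOX5, the enzyme that begins leukotriene synthesis (-1.04 ± 0.17, edgeR adjusted p = 0.0368), HAO2 (-0.83 ± 0.14, edgeR adjusted p = 0.0342) and AHR (-0.77 ± 0.12, edgeR adjusted p = 0.0332). ANXA2, a calcium-dependent membrane-binding protein, missed the threshold at -2.19 ± 0.44 (edgeR adjusted p = 0.0809). PCK1, the rate-limiting enzyme of gluconeogenesis, had a change of 3.62 ± 0.94 that missed it as well (edgeR adjusted p = 0.197). Vitellogenins did not pass the threshold, with changes of 0.02 ± 1.20 for LOC102459916 and -0.54 ± 1.14 for LOC102457264 (edgeR adjusted p = 0.999 and 0.933) and an edgeR adjusted p = 0.995 for LOC102452731.

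Immediate early genes were the 1 list called in females, with 15 of 19 members higher (median 0.76, camera adjusted p = 2.14e-06; adjusted p = 0.995 with an estimated correlation). In this list 2 genes rose, NR4A3 and NR4A1, and 8 when adjusted over the list alone. NR4A2 stood at 2.47 ± 0.56 (edgeR adjusted p = 0.123) and FOSL2 at 0.94 ± 0.25 (edgeR adjusted p = 0.199). The number of lists was 8 without B10 female replicate 1, 6 without B10 female replicate 2, 3 without control female replicate 2 and 2 without control female replicate 1. Other splits of the female samples gave a median of 8 called lists. The genes that rose in females passed no annotation term, with 2 of 20 genes of nuclear receptor activity (adjusted p = 1 by Fisher's exact test). In all, edgeR's quasi-likelihood test called 43 genes in females, 38 higher and 5 lower. Each of the 43 had no overlap between the groups, which chance gives for 10% of genes and which 13.9% of tested genes showed. The split was 5 and 0 with library size scaling and 29 and 9 after quantile normalization. At an unadjusted p under 0.05 there were 1142 genes, and DESeq2 called 303. Without both replicate 6 libraries edgeR called 0 genes (540 at an unadjusted p under 0.05, below the 588 that chance gives). All 43 kept their sign, which is no independent check, as the libraries left were among those that chose them. Without the library labelled control male replicate 5 edgeR called 50 genes, 39 of them among the 43. The list kept its call in both fits, while none of the 14 genes called under the rule for named genes kept it in all 12 fits without 1 library. Single libraries moved the count to 1 (without control female replicate 1), 25 (control female replicate 2), 0 (control female replicate 6, with 717 at an unadjusted p under 0.05), 27 (control male replicate 4), 70 (B10 female replicate 1), 19 (B10 female replicate 2), 25 (B10 male replicate 5) and 14 (B10 male replicate 6).

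Within males, CH25H, which makes the immune oxysterol 25-hydroxycholesterol, rose on the B10 diet by 3.16 ± 0.36 (log2, SE; edgeR adjusted p = 0.0347), from 2.07 ± 0.21 to 18.6 ± 3.86 CPM (SD, n = 3). The other gene called, LOC102459754, is uncharacterized and rose by 2.76 (edgeR adjusted p = 0.0455). It was chosen after its value was seen. NFKBIA and JUNB missed the threshold with changes of 1.35 ± 0.20 and 1.56 ± 0.25 (edgeR adjusted p = 0.0712 for each). So did RND1, which acts on the cytoskeleton, with 2.77 (0.119) and PIM1, a kinase, with 1.23 (0.12). Below the control level but short of the threshold were the ribosome assembly factors BYSL (-1.72 ± 0.24, edgeR adjusted p = 0.0712) and UTP20 (-0.95, 0.129). NGEF, a guanine nucleotide exchange factor (-0.89, 0.0712), VENTX (-2.01, 0.126) and EIF2AK4, the amino acid starvation kinase GCN2 (-0.77, 0.129), were lower without passing it either.

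In males 8 lists were called, 6 higher and 2 lower, and none held with an estimated correlation. Other splits of the male samples gave a median of 5 called lists. Granulocyte markers had all 10 members higher (median 0.91, camera adjusted p = 0.000422; adjusted p = 0.736 with an estimated correlation). Over the list alone 2 rose, and CSF3R stood at 2.14 ± 0.51 (edgeR adjusted p = 0.254). Toll-like receptor and NF-kB genes had 13 of 16 higher (median 0.44, camera adjusted p = 0.0112; adjusted p = 0.736 with an estimated correlation). Over the list alone 4 were up and 2 down. PTGS2, the inducible prostaglandin synthase, stood at 1.68 ± 0.40 and TLR3, a receptor of double-stranded RNA, at 1.39 ± 0.33 (edgeR adjusted p = 0.254 for each). Immediate early genes had 15 of 19 higher (median 0.30, camera adjusted p = 0.0112; adjusted p = 0.902 with an estimated correlation). Over the list alone 2 were up and 1 down, with FOS at 3.06 ± 0.57 (edgeR adjusted p = 0.129). Ribosomal proteins had 60 of 65 lower (median -0.22, camera adjusted p = 5.81e-05; adjusted p = 0.902 with an estimated correlation). Fatty acid oxidation genes had 19 of 26 lower (median -0.23, camera adjusted p = 0.0117; adjusted p = 0.736 with an estimated correlation). Over the list alone 1 of them fell, and CPT1A, the gate of fatty acids into mitochondria, stood at -0.82 ± 0.31 (edgeR adjusted p = 0.453). Erythroid markers had 7 of 7 higher (median 0.65, camera adjusted p = 0.0117). Endothelial markers had 12 of 14 (median 0.30, 0.0281) and stellate cell and fibroblast markers 11 of 15 (median 0.45, 0.0281). Each of these 3 lists had an adjusted p = 0.902 with an estimated correlation. In none of these 8 lists did a gene pass the threshold over all genes.

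By edgeR's quasi-likelihood test these 2 genes were the calls in males, while 1052 genes had an unadjusted p under 0.05 and DESeq2 called 212. Both genes had no overlap between diets, which chance gives for 10% of genes and which 18.4% of tested genes showed. The split of higher and lower calls was 3 and 1 with library size scaling, 15 and 5 on FPKM, 10 and 3 on TPM and 23 and 7 after quantile normalization. It leaned the other way by DESeq2 (97 and 115), with sample weights (1322 and 2380) and among the genes at an unadjusted p under 0.05 by edgeR (480 and 572). Without both replicate 6 libraries edgeR called 0 genes (494 at an unadjusted p under 0.05, below the 588 that chance gives) and the same 8 lists. Without the library labelled control male replicate 5 edgeR called 0 genes (999 at an unadjusted p under 0.05). In that fit endothelial markers changed direction (camera adjusted p = 0.852), and immediate early genes (0.672), erythroid markers (0.672) and stellate markers (0.655) lost their call, and amino acid breakdown (0.0066), antioxidant (0.015) and complement genes (0.0333) were called as higher. Calls were also lost without control male replicate 3 (fatty acid oxidation 0.271, stellate 0.244), control male replicate 4 (Toll-like receptor and NF-kB 0.0569) and B10 male replicate 4 (fatty acid oxidation 0.15, erythroid 0.194, endothelial 0.294, stellate 0.552), which left 4 lists. The gene count was 0 without control female replicate 1, control female replicate 6, control male replicate 3, B10 female replicate 2, B10 male replicate 5 or B10 male replicate 6 (958, 892, 1013, 1090, 674 and 623 genes at an unadjusted p under 0.05). It was 1 without control male replicate 4, 5 without B10 female replicate 1, 6 without B10 female replicate 3 and 11 without B10 male replicate 4.

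Whether the diet acted differently in the sexes was tested directly. TIPARP, CISH, OTOGL, VENTX and PPARGC1A had the same pattern: control females stood lowest, and the log2 change with diet was above 0 in females and below 0 in males (VENTX 2.23 and -2.01, OTOGL 2.46 and -1.26, TIPARP 2.44 and -0.53, CISH 1.40 and -1.22, PPARGC1A 0.85 and -0.77). None of the 5 passed the threshold in males (lowest edgeR adjusted p = 0.126), and PPARGC1A missed it in females (edgeR adjusted p = 0.051). PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, stood at 85.7 ± 10.2 CPM in control and 154.8 ± 9.40 in B10 females, and at 242.8 ± 29.4 in control and 142.5 ± 20.01 in B10 males (SD, n = 3). The difference of diet effects was 1.62 ± 0.22 (log2, SE; edgeR adjusted p = 0.0253). CISH, a feedback inhibitor of cytokine and growth hormone signalling, stood at 99.5 ± 14.5 and 262.3 ± 47.4 CPM in females and at 423.2 ± 133 and 181.8 ± 21.0 in males. The difference was 2.62 ± 0.35 (edgeR adjusted p = 0.0253). For TIPARP the difference was 2.96 ± 0.38, for OTOGL 3.71 ± 0.48 and for VENTX 4.24 ± 0.52 (edgeR adjusted p = 0.0253 for each). Of the opposite sign, ANXA2 (-3.66, edgeR adjusted p = 0.0681), RND1 (-3.42, 0.105), CH25H (-2.42, 0.132), ANO7 (-8.11, 0.147) and STAMBP (-1.04, 0.147) missed the threshold. PCK1 had a difference of 4.54 ± 1.25 that missed it (edgeR adjusted p = 0.278).

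Fatty acid oxidation genes had a higher diet effect in females than in males in 19 of 26 members (median 0.39, camera adjusted p = 0.034; adjusted p = 0.982 with an estimated correlation). PPARGC1A was the 1 member called, and 2 were higher when adjusted over the list alone. ETFDH, of the electron transfer from fatty acid oxidation, stood at 0.99 ± 0.23 (edgeR adjusted p = 0.178). Ribosomal proteins had 57 of 65 members higher (median 0.19, camera adjusted p = 0.0391; adjusted p = 0.982 with an estimated correlation). Erythroid markers had 7 of 7 lower (median -0.77, camera adjusted p = 0.0463; adjusted p = 0.982 with an estimated correlation). No single gene was called in either list, over all genes or over the list alone. These list calls rested on single libraries, and other splits of the samples within each sex gave a median of 7 called lists. The number of lists was 6 without B10 female replicate 2, 5 without control male replicate 4 or B10 male replicate 5, and 1 without control female replicate 2, control female replicate 6, B10 female replicate 3, B10 male replicate 4 or B10 male replicate 6. Camera called none without control male replicate 3 or B10 female replicate 1. The fatty acid oxidation call was lost without control female replicate 2 (0.0905), control male replicate 3 (0.14), B10 female replicate 1 (0.229), B10 female replicate 3 (0.0612) or B10 male replicate 4 (0.125). The ribosomal call was lost without control female replicate 1 (0.723), control female replicate 6 (0.32), control male replicate 3 (0.0885), control male replicate 5 (0.429), B10 female replicate 1 (0.537), B10 female replicate 3 (0.0635), B10 male replicate 5 (0.126) or B10 male replicate 6 (0.084). The erythroid call was lost without control female replicate 2 (0.187), control female replicate 6 (0.0522), control male replicate 3 (0.0885), control male replicate 5 (0.429), B10 female replicate 1 (0.229), B10 female replicate 3 (0.0763), B10 male replicate 4 (0.362) or B10 male replicate 6 (0.0673).

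In all, edgeR's quasi-likelihood test called 9 genes for the difference between sexes, 8 with a higher and 1 with a lower diet effect in females, against 1041 at an unadjusted p under 0.05 and 232 calls by DESeq2. The other 4, chosen after their values were seen, were SAMD4A, MAB21L3, LOC102444904 and LOC102459754. The split was 3 and 1 with library size scaling, 4 and 3 on FPKM, 4 and 2 on TPM and 7 and 3 after quantile normalization. None of the 43 genes called in females was among the 2 called in males, where so few calls leave little room for overlap. In males 24 of the 43 had the same sign, 10 of them with an unadjusted p under 0.05 by edgeR. The diet effects in females and in males had a Pearson correlation across genes of 0.077. Genes are not independent replicates. Without both replicate 6 libraries edgeR called 0 genes (470 at an unadjusted p under 0.05, below the 588 that chance gives) and 2 lists. Without the library labelled control male replicate 5 it called 26 genes, all 9 among them, and 2 lists, fatty acid oxidation (camera adjusted p = 0.00153) and immediate early genes (0.0278). None of the 5 named genes kept its call in all 12 fits without 1 library. Single libraries moved the gene count to 1 (without control female replicate 1), 14 (B10 female replicate 1), 3 (B10 female replicate 2) and 0 (control female replicate 6, control male replicate 4, B10 male replicate 5 and B10 male replicate 6, with 725, 993, 790 and 734 genes at an unadjusted p under 0.05).

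Females and males differed in yolk proteins, among other genes. The vitellogenin gene LOC102459916 was higher in females by 9.29 ± 1.21 (log2, SE; edgeR adjusted p = 0.00206), LOC102452731 by 8.63 ± 1.28 (edgeR adjusted p = 0.00304) and LOC102457264 by 7.31 ± 1.06 (edgeR adjusted p = 0.0027). Over the settings tried, these differences ran from 9.016 to 11.626, from 8.349 to 11.202 and from 7.04 to 9.252. The egg riboflavin-binding protein LOC102455463 was higher by 4.19 ± 0.42 (edgeR adjusted p = 0.000854). FABP1, the liver fatty acid-binding protein, was higher by 8.81 ± 0.78 (edgeR adjusted p = 0.000345). It stood at 816.8 ± 42.2 CPM in control and 1254 ± 950 in B10 females against 4.08 ± 4.99 in control and 1.25 ± 0.49 in B10 males (SD, n = 3). SLC41A1, a magnesium transporter, was higher by 3.77 ± 0.19 (edgeR adjusted p = 9.05e-06). It stood at 677.8 ± 108 and 547.5 ± 188.8 CPM in females and 41.2 ± 4.84 and 48.4 ± 1.92 in males. TMC1, known as a channel of hair cells, had 0 counts in all 6 male libraries and a mean of 13.8 CPM in females, at least 322.5-fold higher given a floor of 3 read pairs, taken as 12 units, over the 6 males.

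The other largest rises (log2) were those of SPATA1 (7.96), TTC22 (4.43), BHLHA15, a transcription factor of secretory cells (4.32), TBATA (4.31), GALNT15 (16.05-fold), BEST3 (3.73) and ZNF367 (3.51; edgeR adjusted p of these 7 at most 0.0348). Without the library labelled control male replicate 5 the values were 7.82 for TTC22, 6.36 for BHLHA15 and 6.15 for BEST3, and without B10 male replicate 6 TTC22 stood at 7.29. TTC22 kept its call in 4 of 12 fits without 1 library and BEST3 in 9. The size of such changes depended on the settings, with a log2 range of 0.963 to 8.358 for SPATA1 and -8.392 to -1.265 for GALR1, a galanin receptor. Lower in females was GALR1 (-6.25 ± 1.17, edgeR adjusted p = 0.00847). So were IGFALS, which carries insulin-like growth factors in plasma (-2.63 ± 0.47, edgeR adjusted p = 0.0069), and ARG1, the last enzyme of the urea cycle (-2.46 ± 0.58, edgeR adjusted p = 0.0217). MAP1B (-3.21), VCAM1 (-3.08), ADAM23 (-2.96), UPP1 (-2.87), AHSG (-2.86) and DDIT4L (-2.68) were also lower (edgeR adjusted p at most 0.0494). Of these, VCAM1 kept its call in 2, UPP1 in 5 and AHSG in 9 of 12 fits without 1 library, and ARG1 in 8, with ARG1 at -1.55 without the library labelled control male replicate 5. SOD2, the mitochondrial superoxide dismutase, was lower in females by -0.78 ± 0.12 (edgeR adjusted p = 0.0041). ESR1, the estrogen receptor, had a sex difference of 0.01 ± 0.38 (edgeR adjusted p = 0.988).

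Of 39 lists, 17 were called between the sexes, 4 higher and 13 lower in females. Other splits of the samples within each diet gave a median of 7 called lists. Endoplasmic reticulum stress genes had all 23 members higher (median 1.33, camera adjusted p = 8.52e-14; adjusted p = 0.372 with an estimated correlation), of which 19 rose and 21 when adjusted over the list alone. DDIT3, a stress-induced transcription factor, rose by 2.96 ± 0.46 (edgeR adjusted p = 0.00369), and HSPA5, the main chaperone of the endoplasmic reticulum, by 1.72 ± 0.30 (edgeR adjusted p = 0.00649). Yolk and egg proteins had 9 of 14 higher, with 5 that rose and 2 that fell (7 and 3 over the list alone; median 0.81, camera adjusted p = 0.0162; adjusted p = 0.372 with an estimated correlation). Ribosomal proteins had 63 of 65 higher with 6 that rose (13 over the list alone; median 0.35, camera adjusted p = 5.9e-11; adjusted p = 0.527 with an estimated correlation), among them RPL12 (0.71 ± 0.14). Heat shock genes had 14 of 20 higher with 3 that rose (3 over the list alone; median 0.22, camera adjusted p = 0.0193; adjusted p = 0.372 with an estimated correlation), among them HSPA8 (0.58 ± 0.14), which kept its call in 10 of 12 fits without 1 library. Annotation terms moved alike: 56 of 171 genes of protein processing in the endoplasmic reticulum rose (10.96 expected, adjusted p = 1.71e-22 by Fisher's exact test), as did 13 of 21 genes of protein export (1.35 expected, adjusted p = 1.41e-08).

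Plasma proteins made by hepatocytes were lower in females; each of the 7 list calls in this paragraph was lost with an estimated correlation (adjusted p = 0.372). Coagulation genes had all 17 members lower, 10 of which fell (12 over the list alone; median -0.98, camera adjusted p = 4.28e-08). Among them were prothrombin, F2 (-1.29 ± 0.17, edgeR adjusted p = 0.00216), and SERPIND1, a thrombin inhibitor (-1.54 ± 0.25, edgeR adjusted p = 0.00422). Complement genes had all 15 lower, 6 of which fell (9 over the list alone; median -0.95, camera adjusted p = 1.06e-05), such as CFI (-1.65 ± 0.34, edgeR adjusted p = 0.0136). Acute phase and plasma proteins had 12 of 13 lower, 7 of which fell (8 down and 1 up over the list alone; median -1.08, camera adjusted p = 0.000123), such as the fibrinogen chains FGA (-1.56 ± 0.31) and FGB (-1.27 ± 0.25). Hepatocyte markers had 8 of 9 lower, with 7 that fell and 1 that rose (8 and 1 over the list alone; median -1.16, camera adjusted p = 0.000213). HNF4A, a master regulator of hepatocytes, was at -1.28 ± 0.24 (edgeR adjusted p = 0.0094) and APOA1, the main protein of high-density lipoprotein, at 1.43 ± 0.30 (edgeR adjusted p = 0.0142). Amino acid breakdown and urea cycle genes had 22 of 25 lower, 8 of which fell (13 over the list alone; median -0.69, camera adjusted p = 1.83e-05), such as AGXT (-1.34 ± 0.20, edgeR adjusted p = 0.00286). Bile acid genes had 11 of 14 lower, 4 of which fell (7 down and 1 up over the list alone; median -0.64, camera adjusted p = 0.00642), such as the bile salt export pump ABCB11 (-0.79 ± 0.20). Genes of the growth hormone axis had 10 of 13 lower, 4 of which fell (7 over the list alone; median -0.54, camera adjusted p = 0.00411), such as the growth hormone receptor GHR (-0.54 ± 0.16, edgeR adjusted p = 0.0469). GHR kept its call in 2 and ABCB11 in 5 of 12 fits without 1 library.

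Markers of other cell types were lower in females as well, in calls that were likewise lost with an estimated correlation (adjusted p = 0.527 for T and NK, endothelial and stellate cells and adjusted p = 0.372 for granulocytes, thrombocytes and antigen presentation). Endothelial markers were lower in 14 of 14 (median -0.81, camera adjusted p = 0.00265), and T and NK cell markers in 8 of 8 (median -0.71, 0.0101). Granulocyte markers were lower in 10 of 10 with 2 that fell (2 over the list alone; median -0.81, 0.00784). Thrombocyte markers were lower in 4 of 4 with 1 that fell, TBXAS1 (2 over the list alone; median -1.12, 0.0283). Stellate cell and fibroblast markers were lower in 14 of 15 with 3 that fell (3 over the list alone; median -0.73, 0.00959), such as the collagen gene COL1A1 (-1.93 ± 0.56, edgeR adjusted p = 0.0483). COL1A1 stood at -1.21 without control male replicate 4 (edgeR adjusted p = 0.104). Antigen presentation genes had 15 of 18 lower (median -0.76, camera adjusted p = 0.0229). RFX5, a regulator of MHC class II genes, fell, while the endoplasmic reticulum chaperones CALR and PDIA3 of the same list rose (2 up and 6 down over the list alone). In the 12 fits without 1 library, RFX5 kept its call in 3, PDIA3 in 5 and COL1A1 in 3. The thrombocyte call was lost without control male replicate 4 (0.0834) or B10 female replicate 1 (0.052), and the stellate call without control male replicate 4 (0.0572).

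**Figure D4:**
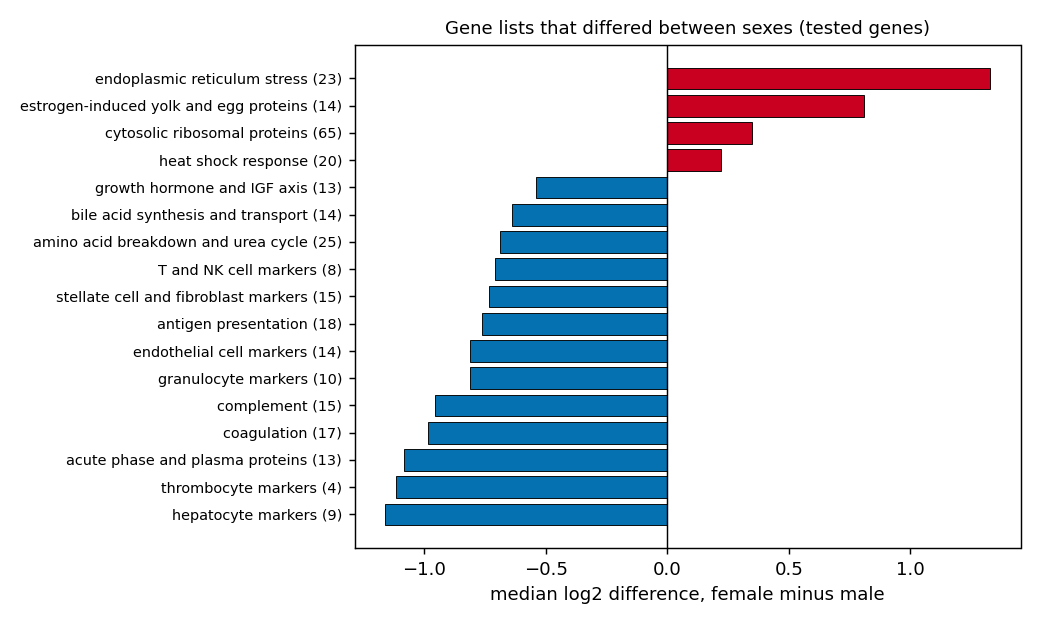
Median log2 difference (female minus male, averaged over diets) of the 17 gene lists that passed the camera test, with the number of tested genes in parentheses; each bar is 1 list. The medians run from -1.16 for hepatocyte markers to 1.33 for endoplasmic reticulum stress genes.

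By edgeR's quasi-likelihood test, 1361 genes differed between the sexes, 733 higher and 628 lower in females, and 591 of them by at least 2-fold. Of the 1361, 808 had no overlap between sexes within either diet, where chance gives 0.5% of genes and 8.4% of tested genes showed it. DESeq2 called 2256 genes. With library size scaling it was 333 higher and 1006 lower, with the median of all genes shifted to -0.18, and on FPKM it was 342 and 1088, with the median at -0.15. No list median changed its sign under the scalings tried. Without both replicate 6 libraries 191 genes were called, 129 higher and 62 lower and 190 of them among the 1361, and the same 17 lists. Without the library labelled control male replicate 5 there were 1355 calls, 686 higher and 669 lower, of which 1099 were among the 1361, and 19 lists, the 17 above with erythroid markers (camera adjusted p = 0.00154) and immediate early genes (0.00425), both lower. Single libraries moved the count to 783 (without control female replicate 1), 639 (control female replicate 6), 2231 (B10 female replicate 3), 811 (B10 male replicate 5) and 678 (B10 male replicate 6).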

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

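The tests of splits of all 12 samples, of mixing, of the female-only transcripts, of library sums and of cell type shares were chosen after the result was seen, and the gene dose test of the library labelled control male replicate 5 was written before it. The splits without replicate 6 were added after the 191 calls and the other splits were seen, but before these splits were run. A direct test of the difference between the sexes singled out 5 named genes and 3 lists. The diet effect was higher in females than in males by 4.24 for VENTX, a homeobox gene, 3.71 for OTOGL, a secreted mucin-like protein, 2.96 for TIPARP, 2.62 for CISH, a cytokine feedback inhibitor, and 1.62 for PPARGC1A, a coactivator of energy metabolism (log2). It was higher by a median of 0.39 for fatty acid oxidation and ketone body genes and 0.19 for cytosolic ribosomal proteins, and lower, at -0.77, for erythroid markers. Of 100 splits of the samples within each sex, 3 gave as many called genes as the real 9, the real one included (highest other 18). Swapping the diet labels in 1 sex alone keeps the 4 groups and exchanges this contrast with the averaged diet effect. That split calls 18 genes here and 9 for the averaged diet by construction. These equal the highest other counts, so those counts do not stand for chance. For the lists 85 of 100 splits gave as many as the real 3 (median other 7, highest other 16), so chance is not excluded.

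For the diet averaged over sexes, 1 of 100 splits, the real one, gave as many genes as the 18 called (highest other 9). That 9 equals the count of the swap in 1 sex. For its 4 lists 75 of 100 splits gave as many (median other 6, highest other 15), which does not exclude chance. For the sex difference 1 of 100 splits, the real one, reached the 1361 genes (highest other 131). Of these 100 splits, 6 reached the 17 lists (median other 7, highest other 19), which does not exclude chance for the lists. With 10 splits within a sex a share under 0.05 cannot be reached. In females 1 split reached the real 43 genes (highest other 2) and 10 the 1 list (median other 8, highest other 11). In males 1 reached the 2 genes (highest other 1) and 2 the 8 lists (median other 5, highest other 9). The real diet grouping thus called fewer lists than the median of the other splits for the averaged diet, in females and for the difference. The real grouping keeps the replicate 6 libraries beside the libraries that they resemble, and most other splits part them, so these gene counts do not decide whether chance is excluded. Without both replicate 6 libraries, 1 of the 100 splits of the 10 samples, the real one, reached its 191 genes for the sex difference (highest other 3), which excludes chance for that result. For the diet results edgeR called 0 genes without these libraries, so no such test was left, and chance stays open. At an unadjusted p under 0.05 by edgeR there were 617 genes for the averaged diet and 470 for the difference, where chance gives 588.

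The replicate 6 libraries of control females and B10 males lie between the other libraries of their group. A single library deposited under a pair of names is argued against by the genes found only in the less similar library of the group, of which 87.6% and 86% were detected. An animal of its own that is alike by chance is argued against by the genes found in neither other library, 2 and 1, against 21 to 40 in the 6 libraries of the other 2 groups. A mixed sample, from RNA or reads of the other libraries, remains a candidate explanation: 5.8% and 4.4% of genes lay beyond 3 standard errors of a weighted sum with weights of 0.75 and 0.25, and 0.683 and 0.317. The deviations from these sums had a robust SD of 1.38 and 1.26 standard errors, against 2.93 to 4.34 in the other 2 groups. Counting noise alone would give 1, so the sums were close but not exact, with 4 units assumed per read pair. Mixing of RNA and mixing of reads were not separated, and no biological explanation was tested.

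The library labelled control male replicate 5 carried the 17 transcripts that the other male libraries lack, at a median of 0.872 of the female mean. Genes on the scaffolds of their close relatives stood at a median of -0.83 (log2) against the other males, near the -0.90 of females. RNA of a female mixed into a male sample is argued against, since vitellogenin would call for a fraction at least 23.5 times smaller than the female-only transcripts do. Some genes named for the sex difference were low in it. TMC1 had 0 counts, and SLC41A1 stood at 46.1 CPM and FABP1 at 9.83 CPM, against at least 329.6 and 367.7 CPM in every female library. These genes were picked with this library counted as male and without overlap between the sexes. Their low values in it were thus required by the choice and do not decide on the label. A mislabelled female animal that lacks this female expression may explain these values, and an animal of female genotype and male appearance, which was not tested, stays open beside it.

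Secretory pathway genes were higher and plasma protein genes lower in females. Without the vitellogenin rows the endoplasmic reticulum stress list stood at a median of 1.34 and the coagulation list at -0.98. That step decides nothing, since TMM factors already trim such extreme genes. Vitellogenin taking a large share of the counts would shift all other genes by about the same amount. The opposite directions of these lists argue against it as the whole cause. A lower share of hepatocytes as the only change is argued against by the markers of 6 other cell types. Their list medians had a median of -0.78 (highest -0.71), where such a share alone would raise them. As CPM values are relative, a lower share beside a rise of other hepatocyte transcripts is not decided by these markers. A biological difference between the sexes may underlie the pattern, as a hypothesis found and tested on the same data. Age, season and body condition of the animals were not tested.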

How the results depend on the processing

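DESeq2, library size scaling, counts divided by 4 and the fits without several libraries were chosen after seeing the data, as was edgeR in place of limma on log2(FPKM + 1), the test planned at first. No called gene changed sign in any setting, and among the lists the endothelial markers in males were the exception. In these lists of counts the order is diet averaged over sexes, diet in females, diet in males, difference of the diet effect between sexes, and sex difference; the main counts are 18, 43, 2, 9 and 1361 genes, 4, 1, 8, 3 and 17 lists and 52 terms. Where no other reason is given, the cause was not tested.

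Under filters, no filter gave 4 genes in males and a stricter filter on mean FPKM gave 7. The robust fit gave 1 in males. A block for the replicate number gave 0, 0, 0, 0 and 4 genes. By the labels, numbers 1 and 2 hold females only, 4 and 5 males only, and 3 and 6 both sexes. The block thus takes up most of the sex difference and leaves few degrees of freedom, so these lost calls do not decide on a pairing. Deviations from the group means were at most weakly alike between samples of the same number (r from -0.122 to 0.135 over 6 pairs). Among samples of other groups, 5 of 12 samples correlated most with that of their own number, so a pairing is not excluded. Fits of only the groups compared gave 5 in females and 7 in males. On log2(FPKM + 1) limma called 12 in females, 20 in males, 2 lists in females and 0 lists for the difference. With a pseudocount of 0.1 it called 10, 5 and 5 genes in females, in males and for the difference, and on TPM 18 in females and 13 in males. After quantile normalization it called 47 genes for the averaged diet and 30 in males, with 2 lists in females, 5 in males and 0 for the difference. Sample weights gave 1671, 296, 3702, 1129 and 5187 genes, as they put 61.5 on control female replicate 6 and 148.9 on B10 male replicate 6 and at most 1.85 on any other library. DESeq2 called 301, 303, 212, 232 and 2256. Library size scaling gave 11, 5, 4 and 4 genes for the diet results.

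Leaving out both libraries midway on the first component gave 18 genes in males, 43 for the difference, 2395 for sex, 7 lists for the difference and 113 terms, and the endothelial markers in males reversed (adjusted p = 0.799). Leaving out both replicate 6 libraries gave 0, 0, 0, 0 and 191 genes (617, 540, 494, 470 and 2191 at an unadjusted p under 0.05) and 11 terms. Chance gives 588 genes at that unadjusted p, so the diet counts were near or below it. The median ratio of log2 changes was 0.99 to 1, so the changes themselves hardly moved. The loss of calls therefore came through the number of samples and the estimated spread, which were not told apart. Libraries close to weighted sums of others narrow that spread by construction. Leaving out both replicate 6 libraries and control male replicate 5 gave 1, 0, 0, 0 and 228 genes (599, 568, 467, 457 and 2150 at an unadjusted p under 0.05), 7 lists for the averaged diet, 5 in males and 8 terms, and the endothelial markers in males reversed (adjusted p = 0.812). The 1 gene for the averaged diet was LOC102463208, annotated as toll-like receptor 5 and chosen after its value was seen. They also reversed without control male replicate 5 alone (adjusted p = 0.852), and the adjusted p of this list ran from 2.59e-05 (without control male replicate 4) to 0.852 over the fits without 1 library.

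A 2-fold change on top of the adjusted p left 591 genes for sex. With the unadjusted p and a 2-fold change there were 293, 461, 414 and 619 genes in the diet results. With an estimated correlation 0, 0, 0, 0 and 0 lists were called by camera. By fry the directional test gave 0, 0, 0 and 0 lists for the diet results and 17 for sex, and the mixed test 2, 6, 3, 6 and 25.

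Leaving out each library in turn gave 1 to 44 genes for the averaged diet, 0 to 70 in females, 0 to 11 in males, 0 to 26 for the difference and 639 to 2231 for sex. Lists ran from 4 to 10, 1 to 8, 4 to 9, 0 to 6 and 15 to 21, and terms from 31 to 80. Of the named genes called, 45 of 73 for sex kept their call in every such fit, and 0 of 6, 0 of 14, 0 of 1 and 0 of 5 for the diet results. For uncalled named genes 327 of 5793 values were stronger, 164 moved and 5302 were the same. Low counts limit the fold of genes near 0, where 1 read pair is taken as 4 units.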

Other observations

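The tests of gene dose on the partner scaffolds, of cAMP and CREB targets and of glucocorticoid targets were chosen after the result was seen, and the test of aryl hydrocarbon receptor targets was written before it. Of 11 genes with a relative of the same annotation among the 17 transcripts of females, 8 were themselves lower in females. The values of these 11 genes come from the edgeR fit without the library labelled control male replicate 5. RAN, a GTPase of nuclear transport, differed by -0.93 (log2, edgeR adjusted p = 0.000465), SBNO1, a helicase-like regulator, by -0.97, ATXN2, an RNA-binding protein, by -1.12, SPPL3, a protease of the Golgi, by -0.92, UBE2L3, a ubiquitin-conjugating enzyme, by -0.88 and RANBP1 by -0.85. EIF4ENIF1 (-0.93) and MSI1 were lower too, while ATP2A2 (-0.40, edgeR adjusted p = 0.12), PITPNB (0.05) and MLEC (0.08) missed the threshold. Sequence likeness of the copies was not tested.

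In all, 12 partner genes, 11 of them tested, lie on 11 scaffolds that hold 89 tested genes. Their median difference between females and the other males was -0.90 (quartiles -1.06 to -0.41), with 81 below 0, against 0 for the rest of the genes. A single copy in females against a pair in males may explain the value of -0.90, as soft-shelled turtles have ZZ males and ZW females. The identity of the scaffolds was not checked against a map.

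TIPARP, a target of the aryl hydrocarbon receptor, rose on the B10 diet in females. As a list of 5, other targets of that receptor tended downward by camera (p = 0.0102 at the preset correlation and p = 0.0705 at an estimated correlation of 0.145). None of the 5 passed the threshold in females. The CYP1A genes LOC102455397, LOC102455640 and LOC106732968 stood at -1.23 ± 0.33, -1.63 ± 0.49 and -0.68 ± 0.42 (edgeR adjusted p = 0.202, 0.267 and 0.65; upper 95% limits -0.59, -0.67 and 0.14). LOC102443979, a UDP-glucuronosyltransferase, stood at -0.48 ± 0.40 (edgeR adjusted p = 0.763) and NQO1, a quinone reductase, at 0.27 ± 0.54 (edgeR adjusted p = 0.931; upper limit 1.33). A joint rise that includes a 2-fold rise of the CYP1A genes is argued against, while a rise of NQO1 alone is not.

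Control females lay below the other groups for several regulators. Over cAMP and CREB target genes without those already called, 13 of 16 had a higher diet effect in females than in males (median 0.97; camera p = 1.51e-06 at the preset correlation and p = 0.00478 at an estimated correlation of 0.0523). Signalling through cAMP may take part, as a hypothesis found and tested on the same data. No other splits of the samples and no fit without the replicate 6 libraries were run for this list, so chance stays open. Over glucocorticoid receptor targets 4 of 8 were higher (median -0.05; camera p = 0.652 at the preset correlation), and members that go both ways decide nothing.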
